A study of Rattus norvegicus with 4 samples.

How the data were processed

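Total RNA of rat spinal cord segments L4 to L6 was hybridised to 1 oligonucleotide array per sample, per the labels, with 2 samples labelled 2 days old and 2 labelled 12 days old. The deposited table holds 1 intensity per probe set and array on a linear scale, for 8728 probe sets, and 1.65% of the intensity values are negative. The software, background correction and summary method by which the authors obtained the intensity values are not given in the sources used here. The grouping and the replicate numbers come from the sample titles, per the labels. All columns of the table belonged to mapped samples, no control probe sets were among them, and the planned ratio of 3' to 5' control signals was therefore not analysed here.

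Gene names came from the array's platform annotation, which can be old, and were updated through gene identifiers to current rat symbols. One gene symbol was given for 6996 probe sets, of which 6975 matched a current gene, several symbols for 308, and 1424 were not named here. No gene was named from a probe set with several symbols. Genome coordinates were not used here. Of the 16 genes set to be reported whatever the result, 14 had a tested probe set with 1 symbol and 2 had none.

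The trimmed means of the arrays, with 2% left out at each end, differed by 15.5%, above the tolerance of 10% fixed before the data were examined, so the deposited intensities were quantile normalized. Values under the pooled 20th percentile, an intensity of 39.6, were set to that floor and log2 transformed, which gives 5.31 at the floor. A probe set was kept where at least 2 of the 4 arrays lay above their own 40th percentile. This left 5432 probe sets, of which 4513 had 1 symbol, for 3316 genes. Among the called probe sets, 19 lay at the floor on both arrays of one label and 36 on 1 array, and a fold against a label wholly at the floor is given as a lower bound. Ranking of the largest differences used only probe sets above the floor on all 4 arrays.

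The ages were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), as the 12-day label minus the 2-day label, two-sided, without a replicate block. P-values were adjusted over all probe sets kept by Benjamini-Hochberg, and a probe set was called at an adjusted p under 0.05. The prior had 4.97 degrees of freedom. Gene lists, 29 in all with at least 5 measured members, covered glia, neurons, transmission, metabolism, growth and other cell types that a dissected segment could hold. Each gene was represented by its probe set of highest mean. Camera in limma with a preset correlation of 0.01 was the test, Benjamini-Hochberg adjusted over the lists, and camera with an estimated correlation and fry were run beside it. Camera called 10 of the 29 lists, fry 10 and camera with an estimated correlation 0, whose lowest adjusted p was 0.344 (limma, Benjamini-Hochberg). With 2 arrays per label that correlation is estimated imprecisely, so a list that this variant does not call is left undecided by it. Of 907 genes with several tested probe sets, 101 had at least 2 called, and 3 genes, Ncam1, Grm7 and Cited2, had calls in both directions.

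The named genes were the 12 with the largest increase and the 12 with the largest decrease past the threshold, up to 4 lower bounds per direction, the 4 members of each list with the smallest p, and the 16 genes reported whatever the result. This gave 135 probe sets of 133 genes, of which 108 probe sets were called. The lists, the rule, the tests and most alternatives were fixed before the data were examined. A list of liver genes, the counts of list members without each array, and a further 15 gene families were added afterwards.

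The fit and the list test were checked on simulated values for 5411 probe sets in the same layout of 2 against 2 arrays. Of 100 probe sets changed by 1 log2 unit 75% were recovered, and of 100 changed by 2 log2 units 91%, with 10 false calls among 176. Camera called the list of changed genes and 0 of 200 random lists. The changes were placed only in kept probe sets with a mean more than 1 log2 unit above the floor, so recovery among dimmer ones was not checked. The noise was drawn from a fit to all 8728 probe sets, with 0.806 prior degrees of freedom, not from the filtered fit. It was independent between probe sets, so this check does not cover lists of genes that vary together. Alternatives changed the normalization, the floor, the filter on dim probe sets, the variance model, the test, the block and the arrays included, one at a time. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.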

Results

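Gene expression was measured in the lumbar spinal cord of neonatal rats with 4 oligonucleotide arrays. Total RNA from segments L4 to L6 was labelled as coming from animals 2 days old on 2 arrays and from animals 12 days old on the other 2. Each array gave 1 intensity for each of 8728 probe sets. The trimmed mean intensity was 180 and 186 on the arrays with the 2-day label and 208 and 190 on those with the 12-day label, and the maximum lay between 7183 and 7649. Negative values numbered between 137 and 150 per array. After quantile normalization, the Pearson correlation across the probe sets kept was 0.974 between the arrays with the 2-day label and 0.948 between those with the 12-day label. Pairs of arrays with different labels correlated between 0.860 and 0.880. These correlations run across probe sets, which are not independent replicates. The labels do not say whether the arrays of one age came from separate animals, so p-values measure only the spread between these samples, which may be technical. The number of arrays, 2 for each age, limits the precision.

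The arrays of the 12-day label differed from each other most in genes known as products of the liver, but not in these alone. For the fixed gene lists the median of replicate 1 minus replicate 2 ran from -0.40 to 0.10 log2 units. The lowest was that of cartilage and bone and the highest that of microglia and macrophages. The list of GABA and glycine transmission lay at -0.23. Of 41 measured genes known as products of the liver, 36 were at least 1 log2 unit higher on replicate 1 than on replicate 2, with a median difference of 3.15. Albumin (Alb) read 3838 on replicate 1 and 77.8 on replicate 2, and alpha-fetoprotein (Afp) read 3250 and 61.7. The arrays of the 2-day label read 20.4 and 71.3 for Alb and 22.0 and 33.8 for Afp. The list of liver genes was written after the difference had been seen. Of its probe sets, 19 were bright enough to be tested between the ages, and 0 passed limma with Benjamini-Hochberg adjustment in either direction. The wide spread of these genes within the 12-day label makes a call hard to reach, so this does not show that the comparison is free of liver transcripts.

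The comparison between the ages asked which genes change in the lumbar cord during early postnatal life. Genes of the myelin sheath gave the largest differences, and they were higher on the arrays labelled 2 days old. The transcript of myelin basic protein (Mbp), a main structural protein of central myelin, had a log2 intensity of 12.75 ± 0.06 (SD, n = 2) at the 2-day label. It was lower on both arrays of the 12-day label, by limma with a log2 difference of -2.75 and a standard error of 0.11, which is 6.71-fold. Genes of growing axons were higher on the arrays labelled 12 days old. Gap43, a protein of the growth cone, had a log2 intensity of 9.26 ± 0.04 (SD, n = 2) at the 2-day label and 10.81 ± 0.02 (SD, n = 2) at the 12-day label, a 2.92-fold difference. Textbook development of the rodent cord runs the other way for both, with myelin transcripts increasing and growth cone transcripts declining after birth. The ages below are therefore those on the labels, and each log2 difference is the 12-day label minus the 2-day label.

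Of 5432 probe sets tested, 422 were higher and 384 lower at the 12-day label by limma with Benjamini-Hochberg adjustment, together 14.8%. At least a 2-fold difference was found for 337 of them, 153 higher and 184 lower. The called probe sets with 1 gene symbol numbered 656 and stood for 532 genes. At an unadjusted p under 0.05 there were 1686 probe sets. The values of the ages did not overlap for 59.6% of the probe sets tested, where chance gives 33.3%. With the values as deposited, 632 were higher and 311 lower, so that 67.0% of the calls were higher against 52.4% after quantile normalization. The median log2 difference of all probe sets tested was 0.08 as deposited and -0.04 after normalization. Fewer probe sets were called whichever array was left out. Such a fit holds 1 array in that label and has less power, so the fall cannot show what any array carried. Of 108 called probe sets among the named genes, 59 kept their call without each array in turn. The call was lost in at least 1 but not all of the 4 fits for Idi1, Mcm6, Cdk4, Syt4, Slc6a9, Kcnd2, Tac3, Mgp, Gjb1, Pmp22, Rplp0, Rpl41, Rps29, Ldhb, Pfkm, Fxyd1, Ndn, Plagl1, H19, Hspb1, Egr1, Klf9, Fgfr2 and others named below. It was lost in all 4 fits for 15 probe sets, among them Mcm7, Rps10 and Atp1b1. At least 1 further probe set did not pass for the called genes Tnc, Cyp51, S100b, Lss, Atp1b2, Hspb1, Fgfr2, Rps29, Pfkm, Gria2, Atp1b1, H19, Pmp22 and Kcnab2, where that of Kcnab2 gave 0.01, and for others given below.

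Among genes above the floor on all 4 arrays, each taken by its brightest probe set, the largest increase toward the 12-day label was in Crmp1, a cytosolic protein of axon guidance signalling. Its log2 difference was 2.49 with a standard error of 0.16, higher on both arrays of that label (limma with Benjamini-Hochberg, adjusted p = 0.000244). Gpc2, a heparan sulfate proteoglycan of developing neurons, was 4.13-fold higher and the actin-binding Coro1a 4.04-fold higher. The tubulins Tubb2b and Tubb5 were 3.91-fold and 3.19-fold higher, and the microtubule-associated Mapt, which encodes tau, was 3.49-fold higher. Basp1, a growth cone protein, rose 3.36-fold, Evl, a regulator of actin filaments, 3.20-fold, Olfm1 3.80-fold and Ctxn1 3.34-fold. Dimmer called probe sets gave smaller differences for Olfm1, at 1.57-fold, and for Tubb5, at 1.95-fold. The glycine receptor subunit Glra2 was 3.74-fold higher and the calcium channel subunit Cacna2d1 3.25-fold higher. The call of Cacna2d1 ended without at least 1 of the arrays, and those of the other 11 held without each array in turn.

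Among genes above the floor on all 4 arrays, each taken by its brightest probe set, the largest decrease was in Ugt8, the enzyme that makes galactocerebroside for myelin. Its log2 difference was -3.30 with a standard error of 0.13, lower on both arrays of the 12-day label (limma with Benjamini-Hochberg, adjusted p = 1.9e-05). The myelin genes Pllp, Mag, Mal and Cnp were 9.22-fold, 8.61-fold, 5.04-fold and 4.6-fold higher at the 2-day label, and another probe set of Mag gave -3.56. The lipid carrier Apod was 7.83-fold higher there, Serinc5 6.44-fold, the lysophospholipase Enpp2 5.62-fold and the glycogen phosphorylase Pygm 5.94-fold. Genes of mature neurons were in the same set, with the calcium-binding protein Pvalb 5.43-fold and the potassium channel Kcna1 4.85-fold higher at the 2-day label. All 12 calls held without each array in turn.

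**Figure D1:**
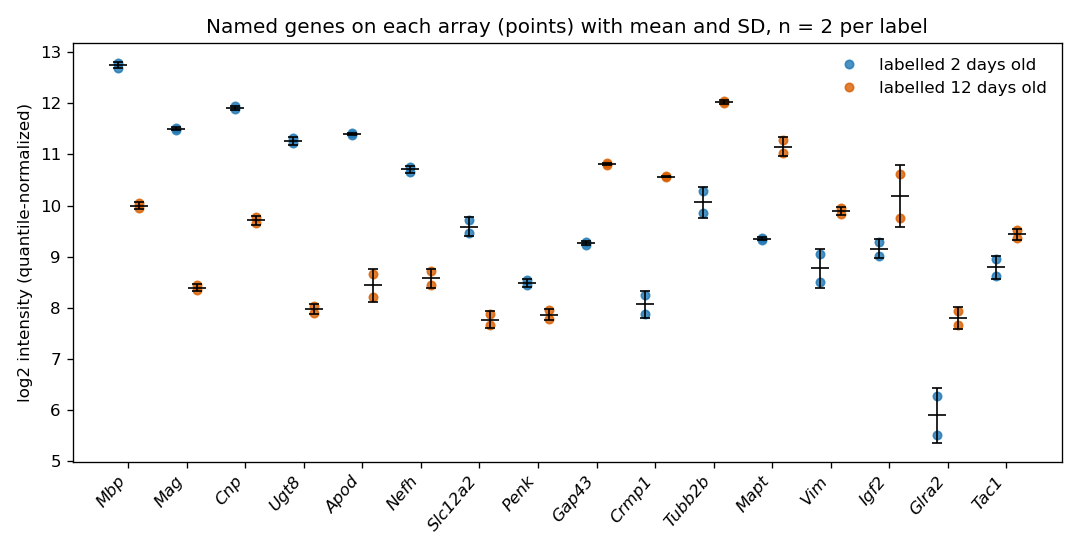
Log2 intensity after quantile normalization of 16 named genes on each array, as points, with the mean and SD of the 2 arrays of each label. Cnp lies near 11.91 at the 2-day label and 9.71 at the 12-day label, and Gap43 lies near 9.26 and 10.81.

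Some probe sets lay at the floor on both arrays of one label, so that their difference is a lower bound. Mobp, a myelin protein, was at least 44.8-fold higher at the 2-day label by 1 probe set. Its other probe sets, with 1 of the 12-day arrays at the floor, gave between 30.7-fold and 58.6-fold. Mog, a protein of the outer myelin surface, was at least 23.2-fold higher by 1 probe set and 31.2-fold by another, with 1 of the 12-day arrays at the floor. The neurotensin receptor Ntsr2 was at least 11.9-fold and Septin4 at least 8.25-fold higher there. In the other direction the retinoic acid-binding protein Crabp1 was at least 7.45-fold higher at the 12-day label. The mitotic kinase Cdk1 was at least 3.41-fold higher. The matrix protein Tnc was at least 3.10-fold higher by 1 probe set. Another probe set of Tnc, with 1 of the 2-day arrays at the floor, gave a log2 difference of 2.18 and passed, while 1 more at 0.45 did not pass. Fcgrt was at least 5.99-fold higher by 1 probe set, while its other probe sets gave -0.07 and -0.06 and did not pass. All 8 bounds passed limma with Benjamini-Hochberg adjustment, and their calls held without each array in turn.

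Genes of myelin and genes of sterol biosynthesis were lower together at the 12-day label. Of 19 measured genes of myelin and mature oligodendrocytes, 16 were lower, 0 were higher and 3 did not pass. Adjusted over the list alone, 17 were lower. The median log2 difference was -2.20, and camera in limma gave a Benjamini-Hochberg adjusted p = 1.09e-17 with the preset correlation and an adjusted p = 0.344 with an estimated correlation. Between 14 and 15 members were past the threshold without each array in turn. Of 14 genes of sterol biosynthesis, all 14 had a negative difference, 7 were past the threshold and, adjusted over the list alone, 12 were lower. The sterol demethylase Cyp51 fell by 1.46 on the log2 scale, lanosterol synthase Lss by 1.52, Msmo1 by 1.17 and the isoprenoid isomerase Idi1 by 0.90. The median was -0.68 (camera in limma, Benjamini-Hochberg adjusted p = 2.19e-07; adjusted p = 0.408 with an estimated correlation). Without 2-day replicate 1, 2-day replicate 2, 12-day replicate 1 and 12-day replicate 2, the number of sterol genes past the threshold was 5, 3, 3 and 7.

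Only 6 genes of oligodendrocyte precursors were measured, and they went both ways. Sox10, a transcription factor of the whole oligodendrocyte lineage, fell by 1.13 and the proteoglycan Bcan by 0.68, while the proteoglycan Cspg5 was higher by 1.29. Ptprz1 gave 0.38 and did not pass. The median was -0.08 (camera in limma, Benjamini-Hochberg adjusted p = 0.805) and turned positive, at 0.04, with the values as deposited. The call of Bcan ended whichever array was left out.

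Astrocyte genes were also lower at the 12-day label. Of 23 measured members 11 were lower, 0 were higher and 12 did not pass. Adjusted over the list alone, 14 were lower and 2 higher. Clusterin (Clu) was 2.76-fold higher at the 2-day label, the water channel Aqp4 of astrocyte endfeet 2.56-fold and the calcium-binding S100b 2.51-fold. The median was -0.54 (camera in limma, Benjamini-Hochberg adjusted p = 2.77e-06; adjusted p = 0.408 with an estimated correlation). The number of members past the threshold was 6 without 2-day replicate 1 and between 8 and 11 without each of the others.

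Some genes of glucose use were lower at the 12-day label as well. Of 15 genes of glycolysis 7 were lower and 0 higher, and adjusted over the list alone 9 were lower and 1 higher. The monocarboxylate transporter Slc16a1 was 2.24-fold higher at the 2-day label, the glucose transporter Slc2a1 2.01-fold, the phosphofructokinase Pfkm 1.79-fold and the lactate dehydrogenase Ldhb 1.59-fold. The median was -0.43 (camera in limma, Benjamini-Hochberg adjusted p = 0.0169; adjusted p = 0.574 with an estimated correlation). Without the arrays in turn the number past the threshold was 1, 2, 1 and 5, in the order 2-day replicates 1 and 2, then 12-day replicates 1 and 2.

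Oxidative phosphorylation genes were lower as a set by a small amount, a shift called only by camera with the preset correlation. Fry did not call it (limma, Benjamini-Hochberg adjusted p = 0.0900). Of 56 measured genes 52 had a negative difference, but 1 was past the threshold, the complex I subunit Ndufv2 at -0.66, and adjusted over the list alone 0 were. By limma, Cox5b at -0.41, Ndufb9 at -0.47 and Ndufa8 at -0.50 did not pass. The median was -0.23 and lay -0.19 below that of all genes (camera in limma, Benjamini-Hochberg adjusted p = 0.00148; adjusted p = 0.463 with an estimated correlation). The call of Ndufv2 ended whichever array was left out. Among 11 sodium and calcium pumps, 3 sodium pump genes were lower and 0 were higher. Atp1b2 fell by 1.29, the pump regulator Fxyd1 by 1.02 and Atp1b1 by 0.52, and Atp2b3 at -0.53 did not pass. Adjusted over the list alone, 4 pumps were lower and 1 higher, with a median of -0.20 (camera in limma, Benjamini-Hochberg adjusted p = 0.119). Without 2-day replicate 1, 1 pump gene was lower, and without each of the other arrays 2 were.

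Transcripts of the immature axon were higher at the 12-day label. Of 24 measured genes of immature neurons and axon growth, 11 were higher, 1 was lower and 12 did not pass. With p-values adjusted over the list alone, 14 were higher and 2 lower. Besides Crmp1, Tubb2b, Basp1 and Gap43, the tubulin-binding Stmn1 was higher by 1.22, the semaphorin receptor Nrp1 by 1.24 and the actin-binding Dbn1 by 1.15. The netrin receptor Unc5b was the member that fell, by 0.65. Stmn1, Nrp1, Dbn1 and Unc5b fall outside the naming rule and were chosen after their values were seen. The median was 0.48 (camera in limma, Benjamini-Hochberg adjusted p = 2.19e-07; adjusted p = 0.408 with an estimated correlation). Between 9 and 11 members were past the threshold as higher without each array in turn, and 0 as lower. Ncam1, a cell adhesion molecule, was higher by 1.66 on one probe set and lower at -0.64 on another, both past the threshold.

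Some genes of dividing cells and progenitors were higher at the 12-day label. Of 24 cell cycle genes 4 were higher at the 12-day label and 0 lower, and adjusted over the list alone 7 were higher. After Cdk1, the replication helicase subunits Mcm6 and Mcm7 were 2.18-fold and 1.65-fold higher and the kinase Cdk4 1.87-fold. By limma with Benjamini-Hochberg, Top2a, a topoisomerase of dividing cells, gave 0.38 with adjusted p = 0.163. The median of the list was 0.35 (camera in limma, Benjamini-Hochberg adjusted p = 0.00066; adjusted p = 0.408 with an estimated correlation). Without the arrays in turn, 1, 5, 3 and 2 members were higher, in the order 2-day replicates 1 and 2, then 12-day replicates 1 and 2. Of 16 genes of neural progenitors and radial glia 2 were higher, Fabp7 by 1.45 and the intermediate filament Vim by 1.11, and adjusted over the list alone 3 were. Fabp5 at 0.41 and Id3 at 0.46 on its brightest probe set did not pass, while another probe set of Id3 at 0.96 did, and the median was 0.10 (camera in limma, Benjamini-Hochberg adjusted p = 0.125). The call of Vim held in 1 of the 4 fits that each left out an array.

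Part of the cytosolic ribosomal protein genes were higher at the 12-day label. Of 37 measured ribosomal protein genes 36 had a positive difference, 17 were past the threshold and 0 were lower. The count was 28 adjusted over the list alone. Rpl41 was 1.84-fold, Rps10 1.70-fold, Rplp0 1.58-fold and Rps29 1.57-fold higher. The median was 0.48 and lay 0.52 above that of all genes (camera in limma, Benjamini-Hochberg adjusted p = 7.16e-12; adjusted p = 0.408 with an estimated correlation). Fewer genes were past the threshold with an array left out: 1 without 2-day replicate 1, 3 without 2-day replicate 2, 4 without 12-day replicate 1 and 2 without 12-day replicate 2.

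Some growth genes of fetal tissue were higher at the 12-day label. Of 13 genes of the insulin-like growth factor system and fetal growth, 5 were higher and 0 lower, and adjusted over the list alone 5 were higher and 1 lower. The imprinted genes Plagl1 and Ndn were higher by 1.15 and 0.90 and the binding protein Igfbp2 by 0.82. The imprinted RNA H19 was higher by 3.98 with a standard error of 0.82 (limma with Benjamini-Hochberg, adjusted p = 0.0207) with 1 of the 2-day arrays at the floor, and had normalized intensities of 7.44 and 53.3 at the 2-day label and 2049 and 256 at the 12-day label. The growth factor Igf2 was higher by 1.03 on 1 probe set (limma with Benjamini-Hochberg, adjusted p = 0.0445), and its other probe sets at 0.14, -0.17 and -0.18 did not pass. The array that read 2049 for H19 is 12-day replicate 1, which also carried the liver transcripts. By limma with Benjamini-Hochberg, H19 was higher by 2.48 without that array, with adjusted p = 0.0127, and Igf2 by 0.61, with adjusted p = 0.118. The median of the list was 0.21 (camera in limma, Benjamini-Hochberg adjusted p = 0.0485; adjusted p = 0.463 with an estimated correlation). Its call ended without 12-day replicate 1 (camera in limma, Benjamini-Hochberg adjusted p = 0.0601) and without 2-day replicate 1 (adjusted p = 0.0757), and without the arrays in turn 0, 1, 3 and 4 members were higher.

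**Figure D2:**
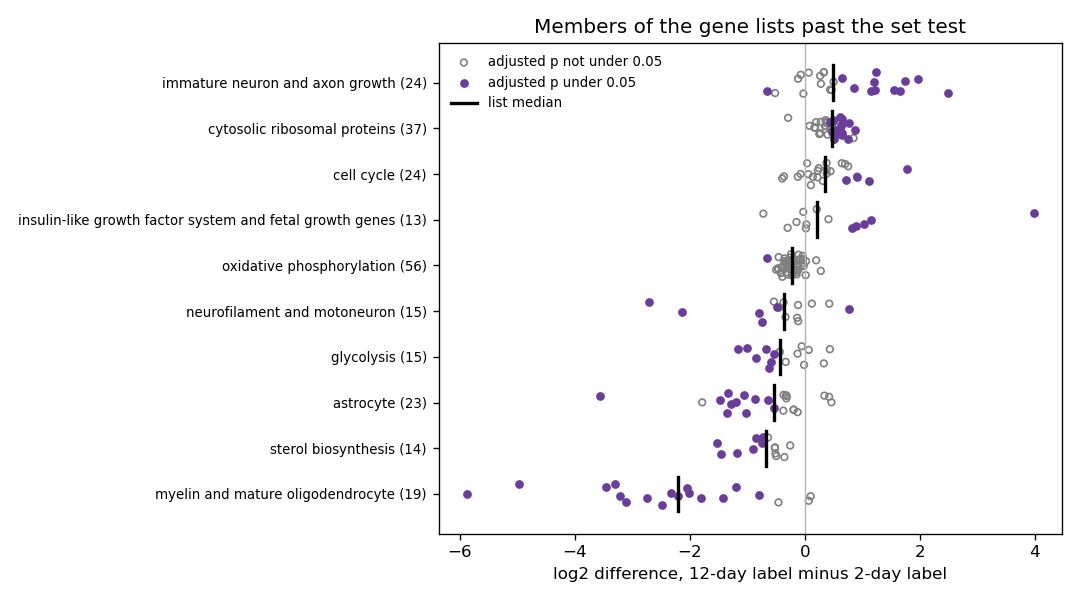
Log2 difference, 12-day label minus 2-day label, of each measured member (points, filled where the adjusted p was under 0.05) of the 10 gene lists past camera's preset-correlation test, with list medians as black lines. The medians run from -2.20 for myelin to 0.48 for immature neurons and ribosomal proteins. The number in brackets is the count of measured members.

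Some neurofilament genes, which accumulate in maturing large axons, were higher at the 2-day label. Of 15 genes of neurofilaments and motoneurons 5 were lower at the 12-day label, 1 was higher and 9 did not pass. The counts adjusted over the list alone were 6 lower and 1 higher. The heavy chain Nefh fell by 2.13, the light chain Nefl by 0.80 and Prph, a filament of peripheral and motor neurons, by 0.49. Spp1 fell by 2.70 with 1 of the 12-day arrays at the floor, and the receptor Gfra1 was higher by 0.77. The median was -0.37 (camera in limma, Benjamini-Hochberg adjusted p = 0.0259; adjusted p = 0.463 with an estimated correlation). Its call also ended with no filter on dim probe sets, with the mean of all probe sets of a gene and with fry. Between 3 and 4 members were past the threshold as lower without each array in turn, and the calls of Prph and Gfra1 ended whichever array was left out.

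Genes of synaptic transmission changed one by one, with no shift of a whole list. Of 30 genes of synaptic vesicles and release 4 were lower and 3 higher, and adjusted over the list alone 6 were lower and 3 higher. The vesicle protein Vamp1 fell by 1.20, its partner Snap25 by 0.92 and Cplx1, a clamp on release, by 1.01, while the calcium sensor Syt4 was higher by 0.93. Without either 2-day array 0 were higher and 3 lower, without 12-day replicate 1 the counts were 2 and 4, and without 12-day replicate 2 they were 1 and 4. The median was -0.10 (camera in limma, Benjamini-Hochberg adjusted p = 0.766) and 0.01 with the values as deposited. Of 20 postsynaptic genes 2 were lower and 0 higher, Dlg1 at -0.87 and Homer3 at -0.96, and adjusted over the list alone 0 were. By limma, Camk2d at 0.51 and Nrgn at -0.43 did not pass, and the median was -0.11 (camera in limma, Benjamini-Hochberg adjusted p = 0.936), which became 0.0063 with the values as deposited. The calls of Dlg1 and Homer3 ended whichever array was left out.

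Few genes of inhibitory transmission passed. Of 24 genes of GABA and glycine transmission 1 was higher, Glra2, the glycine receptor subunit of the immature cord, and 2 were lower, with the same counts adjusted over the list alone. The chloride importer Slc12a2 fell by 1.82, with all 3 of its probe sets past the threshold, and the glycine transporter Slc6a9 fell by 0.93. The chloride exporter Slc12a5 gave 0.03 with a standard error of 0.15 (limma with Benjamini-Hochberg, adjusted p = 0.929). Glra1, the adult glycine receptor subunit, gave 0.24 (limma with Benjamini-Hochberg, adjusted p = 0.505), and a dimmer probe set of it gave -0.90 and passed. Abat at -0.87 did not pass. The median was 0.07 (camera in limma, Benjamini-Hochberg adjusted p = 0.750).

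Of 20 glutamate receptor genes 4 were higher at the 12-day label and 1 was lower, and adjusted over the list alone 5 were higher and 1 lower. The AMPA receptor subunit Gria2 was higher by 0.82, the kainate receptor subunit Grik1 by 1.36 with 1 of the 2-day arrays at the floor, and the NMDA receptor subunit Grin2d by 0.75. The metabotropic receptor Grm7 was lower at -0.81 on its brightest probe set and higher by 1.03 on another. By limma with Benjamini-Hochberg, the NMDA receptor subunits Grin2a, at 0.14 with adjusted p = 0.589, and Grin2b, at 0.06 with adjusted p = 0.806, did not pass. The median was 0.11 (camera in limma, Benjamini-Hochberg adjusted p = 0.111). Of the 4 fits that each left out an array, 1 kept the calls of Gria2, Grik1 and Grin2d, and 0 kept that of Grm7. Without 12-day replicate 1, 4 glutamate receptor genes were higher and 0 lower, and without any other array 0 were either.

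Voltage-gated channels differed in both directions, 5 higher and 6 lower of 36, and adjusted over the list alone 6 and 6. The sodium channels went apart, with Scn1a lower at -1.89 and Scn2a higher by 1.39. Among potassium channel genes Kcna1 and the subunit Kcnab2, at -1.22, were lower, and Kcnd2, at 1.12, was higher. Scn2a was chosen after its value was seen. The counts were 1 higher and 3 lower without 2-day replicate 1, 3 and 3 without 2-day replicate 2 or 12-day replicate 1, and 3 and 4 without 12-day replicate 2. The median was -0.09 (camera in limma, Benjamini-Hochberg adjusted p = 0.750).

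Peptides of the dorsal horn also went both ways. Of 25 neuropeptide and opioid receptor genes 5 were lower at the 12-day label and 2 higher, and adjusted over the list alone 10 were lower and 3 higher. The peptide Adcyap1 fell by 2.01, the tachykinin Tac3 by 1.18 and the enkephalin precursor Penk by 0.62. The other probe sets of Adcyap1, at 0.56 and 0.49, pointed the other way and did not pass. The substance P precursor Tac1 was higher by 0.65 and the neurotrophin receptor Ntrk2 by 1.24. The median was -0.29 (camera in limma, Benjamini-Hochberg adjusted p = 0.103). Without each array in turn 1 peptide gene was higher, and 2, 3, 4 and 5 were lower, in the order 2-day replicates 1 and 2, then 12-day replicates 1 and 2. The calls of Penk and Tac1 ended whichever array was left out. Of 20 neurotrophin and receptor genes 3 were higher, Ntrk2, Gfra1 and the secreted Vgf at 0.56, and 1 was lower, the growth factor receptor Fgfr2 at -0.78, with the same counts adjusted over the list alone. The median was -0.13 (camera in limma, Benjamini-Hochberg adjusted p = 0.797), and the call of Vgf ended whichever array was left out. With each array left out 1 neurotrophin gene was higher, and 1 was lower only without 12-day replicate 2.

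Lists for other cell types that a dissected segment could hold did not pass camera in limma after Benjamini-Hochberg adjustment with all 4 arrays. With an array left out some did: erythroid and Schwann cell genes without 2-day replicate 1, meninges without 2-day replicate 2, microglia without 12-day replicate 1, and endothelium, meninges, erythroid, muscle and cartilage genes without 12-day replicate 2. Fry, which tests whether the genes of a list move one way and not whether they differ from other genes, called the erythroid and Schwann cell lists, and also the pumps and the neuropeptides. Of 6 erythroid and blood genes 2 were higher, the globins Hbb by 1.01 and Hbb-b1 by 0.92, whose probe sets can bind each other's near-identical transcripts. Alas2 at 0.57 and Epor at -0.16 did not pass, and adjusted over the list alone 3 were higher (median 0.29, camera in limma with Benjamini-Hochberg, adjusted p = 0.0614). Of 9 Schwann cell and nerve root genes 4 were lower, Mal, Sox10, Gjb1 at -1.42 and Pmp22 at -0.74, the first 3 of which oligodendrocytes also express. Adjusted over the list alone 4 Schwann cell genes were lower and 1 higher (median -0.24, camera in limma with Benjamini-Hochberg, adjusted p = 0.0917). Of 10 cartilage and bone genes Spp1 was lower, also adjusted over the list alone, while Bglap at -0.64, Col9a1 at -0.90 and Sparc at -0.37 on its brightest probe set did not pass (median -0.30, camera in limma with Benjamini-Hochberg, adjusted p = 0.0910). Of the 3 other probe sets of Sparc, both at -0.85 passed and that at -0.65 did not. Of 7 dorsal root ganglion genes Tac1 was higher and Prph lower, also adjusted over the list alone, while Isl2 at 0.43 and Scn11a at -0.84 did not pass. Their median was 0.04 and their mean -0.08 (camera in limma, Benjamini-Hochberg adjusted p = 0.989).

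Vascular, immune and meningeal lists held single differences. Of 15 genes of endothelium and pericytes 3 were lower at the 12-day label, Slc2a1, the efflux pump Abcb1a at -0.95 and the smooth muscle protein Tagln at -0.80, and 0 were higher. Myh11 at -0.71 did not pass, and adjusted over the list alone 4 were lower (median -0.19, camera in limma with Benjamini-Hochberg, adjusted p = 0.0910). Of 13 genes of microglia and macrophages the protease Ctss was lower at -1.49, also adjusted over the list alone, while RT1-Db1 at -0.59, RT1-Da at -0.34 and Cd14 at -0.27 did not pass (median -0.26, camera in limma with Benjamini-Hochberg, adjusted p = 0.103). Of 22 genes of meninges and fibrous matrix 3 were higher, Igf2, Igfbp2 and the collagen Col3a1 by 0.96, and the matrix protein Mgp was lower at -1.49, with the same counts adjusted over the list alone. The median of the meningeal genes was 0.22 (camera in limma, Benjamini-Hochberg adjusted p = 0.259). Without 2-day replicate 1 or 12-day replicate 1, 0 vascular genes were lower and 0 meningeal genes higher. The calls of Slc2a1, Abcb1a, Tagln, Igf2, Igfbp2 and Col3a1 each held in 1 of the 4 fits that left out an array.

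Of 16 skeletal muscle genes 2 were lower, Pygm and Pvalb, which glia and neurons of the cord also express, and 1 was higher, the actin Acta1 by 1.17 with 1 of the 2-day arrays at the floor. These counts stood adjusted over the list alone, Des at -0.52 did not pass, and the median was -0.18 (camera in limma, Benjamini-Hochberg adjusted p = 0.209). Of 20 immediate early and stress genes 3 were lower, the small heat shock protein Hspb1 at -0.97, the transcription factors Egr1 at -0.95 and Klf9 at -0.92, and 1 was higher, the phosphatase Dusp6 by 0.89, with the same counts adjusted over the list alone. The median was -0.28 (camera in limma, Benjamini-Hochberg adjusted p = 0.125). The other probe sets of Egr1, at -0.32 and -0.05, did not pass. Without 2-day replicate 2, 0 of the stress genes passed, and without 2-day replicate 1, 1 did. The calls of Acta1 and Dusp6 ended whichever array was left out.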

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

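The list counts without each array were chosen after seeing the data, and the other alternatives were planned. All 806 calls kept their direction under 3 other scalings and 3 treatments of low values. The 3 filters, 2 variance models, ordinary t-test and replicate block leave the log2 difference of a probe set unchanged, so they cannot test direction. All calls also kept it without each array in turn, which cannot turn a probe set whose ages do not overlap. Against 422 higher, 384 lower and 337 with a 2-fold difference, the counts were lower with no filter: of all 8728 probe sets, 884 at the floor on all 4 arrays, 24 were higher, 53 lower and 56 of 2-fold size, and the prior fell to 0.806 degrees of freedom. An ordinary t-test, which borrows no variance between probe sets, gave 5 higher, 6 lower and 6 of 2-fold size. The 2-fold count was 215 with a pseudocount in place of the floor and 180 with a filter at the 60th percentile, where 3686 probe sets were tested. Without each array in turn, where a lone array is assumed to vary like the other label's pair, 110 to 222 were higher and 155 to 279 lower.

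A replicate block gave 399 higher and 365 lower, and 711 of the 806 calls were shared. Same-numbered arrays shared only a number, their deviations correlating at -0.078 across probe sets. The block added the erythroid, Schwann cell and cartilage lists to the 10 called. The fetal growth list lost its call with the values as deposited, with no filter, with a floor at the 40th percentile, and without 2-day or 12-day replicate 1. The neurofilament list lost it with no filter and with the mean of all probe sets of a gene. Fry ended 4 of the 10 calls, those of the neurofilament, oxidative phosphorylation, glycolysis and fetal growth lists, and added those of the neuropeptide, erythroid, Schwann cell and pump lists. The mean of all probe sets added the endothelium and erythroid lists. Leaving out an array added erythroid and Schwann cell genes (2-day replicate 1), meninges (2-day replicate 2), microglia (12-day replicate 1), and endothelium, meninges, erythroid, muscle and cartilage genes (12-day replicate 2, with 15 lists called).

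Signs turned, or a median reached 0, only in values that had not passed their test with all 4 arrays, and the cause was not tested. With the values as deposited, the median was 0.038 for oligodendrocyte precursors, 0.013 for synaptic vesicles and 0.0063 for postsynaptic genes. With no filter it was 0.10 for oligodendrocyte precursors and 0 for neuropeptides. Without each array in turn, Epor ran from -0.49 to 0.18 and Slc12a5 from -0.14 to 0.19, with -0.01 without 12-day replicate 2. The list medians then ran from -0.16 to 0.034 for synaptic vesicles, -0.10 to 0.26 for meninges, -0.18 to 0.025 for oligodendrocyte precursors, -0.12 to 0.010 for postsynaptic genes, -0.18 to 0.037 for channels, -0.40 to 0.052 for muscle and -0.12 to 0.093 for dorsal root ganglion. Of the 108 called named probe sets, 62, 73, 77 and 81 kept their call without 2-day replicates 1 and 2 and 12-day replicates 1 and 2. All 4 fits kept 59, and 15 were kept in none. Signal near the floor limits dim genes, for which only bounds were given.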

Other observations

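The tests on the age labels and on liver transcripts, and the 15 gene families, were chosen after the results had been seen. Those on ribosomal and oxidative phosphorylation genes were written before they were run, but they name the directions in which these lists shifted. Among the families, 3 passed camera in limma after Benjamini-Hochberg adjustment. Of 15 splicing factors and hnRNPs 5 were higher at the 12-day label and 0 lower, with a median of 0.47 (camera in limma, Benjamini-Hochberg adjusted p = 0.000566; adjusted p = 0.691 with an estimated correlation). The RNA-binding Hnrnpa1 was higher by 1.11, the spliceosome protein Snrpd3 by 0.90 and Srsf2 by 0.81. Of 10 genes grouped here as histones and chromatin proteins 3 were higher, with a median of 0.51 (camera in limma, Benjamini-Hochberg adjusted p = 0.0117, and adjusted p = 0.691 with an estimated correlation). The 3 were the deacetylases Hdac2 by 0.99 and Hdac6 by 0.91 and the histone H2ax by 0.80. The grouping does not show that each member acts on chromatin.

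Of 12 genes of fatty acid synthesis and elongation 6 were lower at the 12-day label and 1 was higher, with a median of -0.55 (camera in limma, Benjamini-Hochberg adjusted p = 0.0117; adjusted p = 0.691 with an estimated correlation). The desaturases Scd and Scd2 fell by 1.90 and 1.31, the acyl-CoA synthetases Acsl6 and Acsl3 by 1.72 and 1.63, the elongase Elovl5 by 1.01 and the fatty acid synthase Fasn by 0.67, while Acsl4 was higher by 1.09. None of 26 proteasome subunits passed limma with Benjamini-Hochberg, with a median of 0.12 (camera in limma, Benjamini-Hochberg adjusted p = 0.157).

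Many markers of tissue maturation ran against the age labels, as did the medians of all 8 lists picked after the pattern was seen. That count decides nothing by itself and leaves out the GABA and glycine list at 0.07 and the glutamate receptors at 0.11. Among the 8, the neural progenitor list at 0.10 did not pass (camera in limma, Benjamini-Hochberg adjusted p = 0.125). The fetal growth list at 0.21 lost its call under some alternatives. Of 12 genes reported whatever the result, given textbook directions once their values were known, 7 passed limma with Benjamini-Hochberg on their brightest probe sets. Against the labels ran 6 of these (Mbp, Nefh, Gap43, Vim, Glra2 and Igf2). Slc12a2, known to decline in neurons after birth, ran with the labels at -1.82. A dimmer probe set of Glra1 passed at -0.90, against the labels. The other probe sets of Igf2, at 0.14, -0.17 and -0.18, did not pass. Igf2 gave 0.61 on its called probe set without 12-day replicate 1. A single mislabelled array is argued against, since the lowest correlation between arrays of one label was 0.948 and the highest between labels 0.880. For the myelin list, normalization, floor and filter are argued against as well, since its median stayed at or below -2.02 under each of them. This check used the myelin list alone, whose differences are large, so it does not cover the smaller shifts of the other lists. An exchange of the age labels of both pairs stays open, as does an unknown difference between the animals. No independent record of age was used here. Slc12a2 does not decide against an exchange, since its known decline is in neurons and the RNA came from cord segments, not neurons alone.

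Liver transcripts stood out on 12-day replicate 1. Of 41 measured liver genes 87.8% were at least 1 log2 unit higher there than on replicate 2, against 117 of all 4731 genes. Intensities there included Alb at 3838, Afp at 3250, Ahsg at 3149, Serpina1 at 2924 and Hp at 2906, and on the other 3 arrays 15 of the 41 were at the floor and 8 lay above the 40th percentile. An acute phase response of the cord itself is argued against, since the 25 liver enzymes and carriers that are not acute phase proteins differed by a median of 3.02. Liver RNA in that sample is a candidate explanation, by a route that the labels do not record.

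At the 12-day label 17 of 37 ribosomal genes and 1 of 56 oxidative phosphorylation genes were past the threshold. As sets, the first shifted up and the second down by camera with the preset correlation. With an estimated correlation neither passed (camera in limma with Benjamini-Hochberg, adjusted p = 0.408 and 0.463). Fry called the ribosomal set and not the other (limma, Benjamini-Hochberg adjusted p = 0.0292 and 0.0900). A shift of all bright probe sets is argued against for both. The ribosomal median of 0.48 lay at percentile 100 of 10000 random lists matched on brightness, whose central 99% ran from -0.31 to 0.10. The oxidative phosphorylation median of -0.23 lay at percentile 0.03 of its matched lists, which ran from -0.17 to 0.12. A biological difference between the ages stays open, as untested.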
